A study of Trichoderma atroviride with 9 samples.

How the data were processed

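RNA was sequenced from mycelium of Trichoderma atroviride IMI206040 on day 3 in 9 libraries, 3 for each of control, 0.1 mM and 0.5 mM phosphite, all with 1 mM phosphate. Per the labels' protocols, RNA was extracted with TRIzol and paired-end libraries were made with an MGIEasy kit. Per the submitters' processing notes, FastQC 0.11.8, HISAT2 and featureCounts were used. Versions of the last pair of tools, the settings, the genome build, the annotation and the use of strand are not given in the sources used here.

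The values the authors deposited are estimated counts, that is counts per transcript model with fractions of a read and no normalisation. The unit was read from the values, since column totals differ and many values are not whole within a tolerance of 0.02. Of those that are not whole, 92.7% lie at a multiple of 1 over 12 to within rounding. A half-read step holds 40.0%. Reads that belong to several models were thus divided among them, although the rule used is not stated. Overlapping genes, antisense genes and near-identical copies cannot be separated with certainty. Of all genes, 92.5% had a value that was not whole in some library. Whole-number counts had been assumed when the tests were chosen, and the count test was kept after rounding.

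The table held 12453 rows for 12181 genes. There were 226 genes with several rows, up to 7, and the rows of each such gene were identical within 0.02. Rows were summed per gene and rounded to whole numbers. All measured columns were mapped to samples by name. Gene identifiers were used as deposited. None of the 13312 rows of the gene table given for reference, which describes another strain, matched them: 0 identifiers were found, and the file does not pair identifiers with names. Gene lists fixed for phosphate acquisition, the cell cycle, replication, cell wall, transport, stress and other processes therefore could not be filled, and their tests were not run.

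Counts were analysed in edgeR 4.0.16 with limma 3.58.1 on R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 10384 genes and removed 1797. Libraries were scaled by TMM factors, dispersions were estimated with estimateDisp and glmQLFit with robust fitting, and contrasts were tested two-sided with glmQLFTest. All 9 libraries entered a joint fit, and the common biological coefficient of variation was 0.12. Contrasts were each dose against the control, 0.5 mM against 0.1 mM, and the mean of both doses against the control. Calls used a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Standard errors were obtained from the log2 fold change and the F statistic. Normalised counts are counts divided by the effective library size and multiplied by 17962232, the geometric mean of the effective sizes. Log2 CPM (counts scaled to library size) for correlations and components used a prior count of 2. Patterns over the doses were read from the calls of the contrasts.

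The groups, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. By that rule, for genes without a functional name, up to 2 per direction and comparison were named, those with the largest fitted fold among genes with an adjusted p under 0.05, a mean of at least 50 normalised counts in a compared group and libraries that did not overlap. For a gene with no count in a group, the mean normalised count of the other group was divided by the normalised value of 3 counts over the group. With 1 to 3 counts, the ratio is given with an exact 95% interval. Such intervals and floors cover counting error only.

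Depth ranged from 10447623 to 112828508 counts per library. A floor of 3 counts over a group corresponds to 1.37 normalised counts in the control, 0.381 at 0.1 mM and 0.991 at 0.5 mM. The procedure was tested on simulated data in 10268 genes, with the depths of the libraries and each gene's mean share over all libraries. For 0.1 mM against control, with 200 changed genes, it recovered 61.2% of 1.5-fold, 89.6% of 2-fold and 100.0% of 4-fold changes, with 5.6% false calls. For 0.5 mM against control the shares were 55.2%, 83.6% and 98.5%, with 6.0% false. For 0.5 mM against 0.1 mM, with 400 changed genes, they were 62.7%, 89.6% and 100.0%, with 6.4% false. For the mean of both doses, 9.7% of 1.22-fold, 56.7% of 1.41-fold and 90.9% of 2-fold changes were recovered, with 6.3% false. These shares came from a single run in which far fewer genes changed than were called in the data. Scaling and false calls at the share of genes called in the data were therefore not tested. Each gene was also given the same dispersion in all groups. Real replicate pairs differed by a median log2 value of 0.178 to 0.238 in the control and 0.082 to 0.126 at 0.5 mM. False calls under such unequal spread were not tested. Shared controls were simulated 50 times with unchanged groups.

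Alternatives were DESeq2 1.42.0, other scaling factors, other low-count filters, no robust fitting, a fold minimum, the replicate number as a block, fits of the compared groups alone, and leaving out each library. Added after seeing the data were transcript rows in place of genes, replicate 1 at 0.1 mM thinned to the depth of replicate 2, both doses as a joint group, and the counts by dose pattern, and of genes highest or lowest at 0.1 mM, under the alternatives. Tables were prepared with pandas 2.3.3 and numpy 2.4.6 on Python 3.11.15, and plots with matplotlib 3.10.9.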

Results

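Messenger RNA was profiled by sequencing in mycelium of the wild-type strain IMI206040 of Trichoderma atroviride, a soil ascomycete and mycoparasite used in biological control. Cultures were sampled on day 3. The control medium held 1 mM phosphate, and the treated media held the same phosphate plus phosphite at 0.1 mM or at 0.5 mM. Phosphite is a reduced relative of phosphate that most organisms cannot use as a source of phosphorus. Each of the 3 groups had 3 libraries. The title of the series names growth, the cell cycle and cell division, but the gene models carry identifiers without names, so those gene groups were not analysed here and genes are described by identifier and by pattern over the doses.

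The 9 libraries held 13551026, 12797250 and 15431832 counts in the control, 112828508, 11295655 and 12140981 at 0.1 mM phosphite, and 22320306, 20216901 and 10447623 at 0.5 mM. Replicate 1 at 0.1 mM was 5.05 times as deep as the next deepest library. It detected 93.4% of the 12181 genes with at least 10 counts, against 81.6% to 86.6% in the other libraries. The 10 most abundant genes of each library took 7.33% to 11.37% of its counts, with the highest share in control replicate 3. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom between 2.19 and 66.98. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

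Libraries grouped by treatment. Pearson correlations of log2 CPM (counts scaled to library size), taken across genes, which are not independent replicates, were 0.983 to 0.997 within groups. Between groups they were 0.927 to 0.948 for control and 0.1 mM, 0.904 to 0.917 for control and 0.5 mM, and 0.948 to 0.956 for the 2 doses. The first principal component, with 62.4% of the variance, ordered the groups by dose. The second component, with 24.5%, separated the 0.1 mM libraries, at -38.95 to -36.20, from both the control libraries, at 8.50 to 21.54, and the 0.5 mM libraries, at 22.75 to 26.79.

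**Figure D1:**
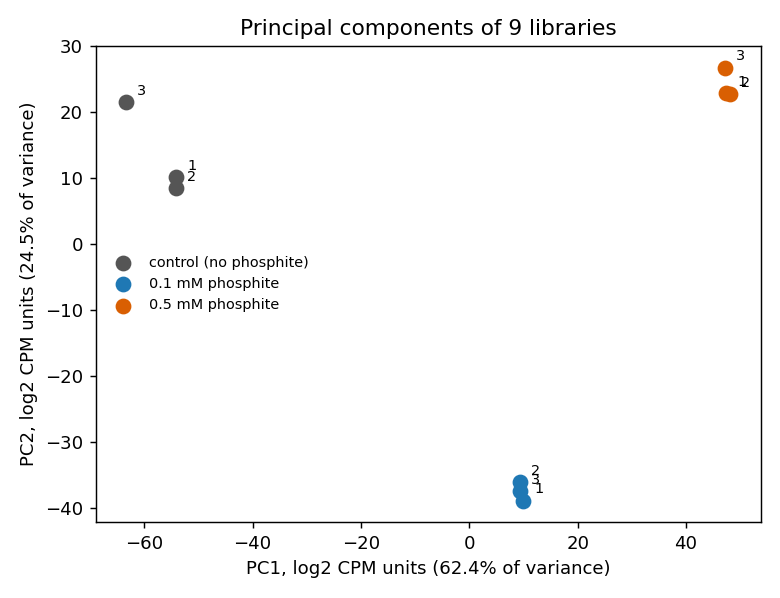
Principal components of log2 CPM in the 9 libraries, with 1 point per library, colour for the group and the replicate number beside the point. The horizontal axis is the first component (62.4% of the variance) and the vertical axis the second (24.5%). The 0.1 mM libraries lie between the other groups on the first axis and below both on the second.

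The first comparison asked which genes changed at 0.1 mM phosphite. Of 10384 genes tested, 4653 (44.8%) changed, 2312 higher and 2341 lower than in the control. Large changes were more often increases: of 1355 genes that changed at least 2-fold, 933 were higher and 422 lower, and of 448 that changed at least 4-fold, 330 were higher and 118 lower. The median size of change among all called genes was 1.56-fold. With genes sorted into 4 equal bins of expression, the lowest bin held the highest shares of 2-fold changes, with 17.1% higher and 7.4% lower, against 5.1% and 3.3% in the highest bin.

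Among the gene models with the largest increases at 0.1 mM, Tatro_004038 had no count in any of the 3 control libraries and 63.3 ± 10.9 normalised counts at 0.1 mM (SD, n = 3). Set against a floor of 3 counts over the control group, or 1.37 normalised counts, this mean was at least 46.4-fold higher, with an adjusted p of 3.8e-06 in edgeR's quasi-likelihood test. Tatro_012373 was the other, with 60 ± 13.8 normalised counts in the control and 11400 ± 99.3 at 0.1 mM. Its log2 fold change was 7.57 ± 0.15 (SE), or 190-fold, with an edgeR adjusted p of 4.4e-11. At 0.5 mM it reached 6310 ± 312, a log2 fold change of -0.85 ± 0.11 from its level at 0.1 mM (edgeR adjusted p of 5.6e-05).

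The largest decreases at 0.1 mM were in Tatro_007317 and Tatro_005432. Tatro_007317 stood at 275 ± 85.0 normalised counts in the control and at 1.95 ± 1.70 at 0.1 mM (SD, n = 3), a log2 fold change of -6.74 ± 0.36 (SE; edgeR adjusted p of 6.1e-08). The log2 fold change of Tatro_007317 was -7.39 without replicate 1 at 0.1 mM and -6.05 with that library thinned to the depth of replicate 2. Tatro_005432 went from 90.9 ± 20.3 to 2.13 ± 0.674 normalised counts, a log2 fold change of -5.42 ± 0.33 (edgeR adjusted p of 1.4e-07). Both genes were also low at 0.5 mM, at 1.93 ± 0.362 and 0.836 ± 0.865 normalised counts, and no difference between the doses was called for either.

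The calls at 0.1 mM came from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. For 5330 of the 10384 genes (51.3%) the 3 control and 3 treated libraries did not overlap, where chance gives 10%. Scaling by library totals alone moved the median log2 fold change of all genes by 0.127, and the higher share of the calls was then 66.7% in place of 49.7%.

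The same question at 0.5 mM phosphite gave 5613 changed genes (54.1%), 2861 higher and 2752 lower than in the control. At least 2-fold changes were seen in 1987 genes, 1213 higher and 774 lower. At least 4-fold changes were seen in 700, of which 446 were higher and 254 lower. The median change of the called genes was 1.69-fold. As at the lower dose, 2-fold changes were most frequent in the lowest bin of expression, with 21.3% of genes higher and 12.2% lower, against 7.1% and 6.4% in the highest bin.

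Tatro_009722 had no count in the 3 control libraries, 8.57 ± 5.63 normalised counts at 0.1 mM and 231 ± 17.2 at 0.5 mM (SD, n = 3). Against the floor of 3 counts over the control group it was at least 169-fold higher at 0.5 mM (edgeR adjusted p of 1.2e-07). Tatro_004038, named above for its increase at the lower dose, rose further to 112 ± 23.1 normalised counts, at least 81.8-fold above the same floor (edgeR adjusted p of 6.0e-07).

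The largest decreases at 0.5 mM were in gene models that had not fallen at 0.1 mM. Tatro_005475 held 632 ± 118 normalised counts in the control, 857 ± 103 at 0.1 mM and 0.831 ± 0.857 at 0.5 mM (SD, n = 3). It had 3 counts in all at 0.5 mM against 1382 in the control, a ratio of 635 between the depth-scaled totals with a 95% interval of 217 to 3080 that covers counting error only (edgeR adjusted p of 7.3e-10). Its fitted log2 fold change was -9.20, and -9.99 without replicate 2 at 0.5 mM. At 0.1 mM the same gene was higher than in the control by 0.45 ± 0.14 on the log2 scale (edgeR adjusted p of 0.023). Tatro_005137 went from 955 ± 147 in the control and 978 ± 51 at 0.1 mM to 5.65 ± 2.89 at 0.5 mM, a log2 fold change of -7.47 ± 0.24 from the control (edgeR adjusted p of 3.6e-10).

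Switches between near absence and clear expression were few. At 3 counts or fewer over the control libraries and at least 50 normalised counts at 0.5 mM there were 7 genes, 2 of them with no control count, and 1 gene met the same bounds at 0.1 mM. In the other direction, 2 genes with at least 50 normalised counts in the control had 3 counts or fewer at 0.5 mM, and 0 genes did at 0.1 mM, where the deepest library sets a lower floor. Of the 10 most abundant genes, 4 were higher and 2 lower at 0.1 mM, and 5 were higher and 4 lower at 0.5 mM.

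At 0.5 mM, 6594 of 10384 genes (63.5%) had control and treated libraries that did not overlap, where chance gives 10%. Scaling by library totals alone moved the median log2 fold change by 0.11 and made 61.7% of the calls higher in place of 51%.

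**Figure D2:**
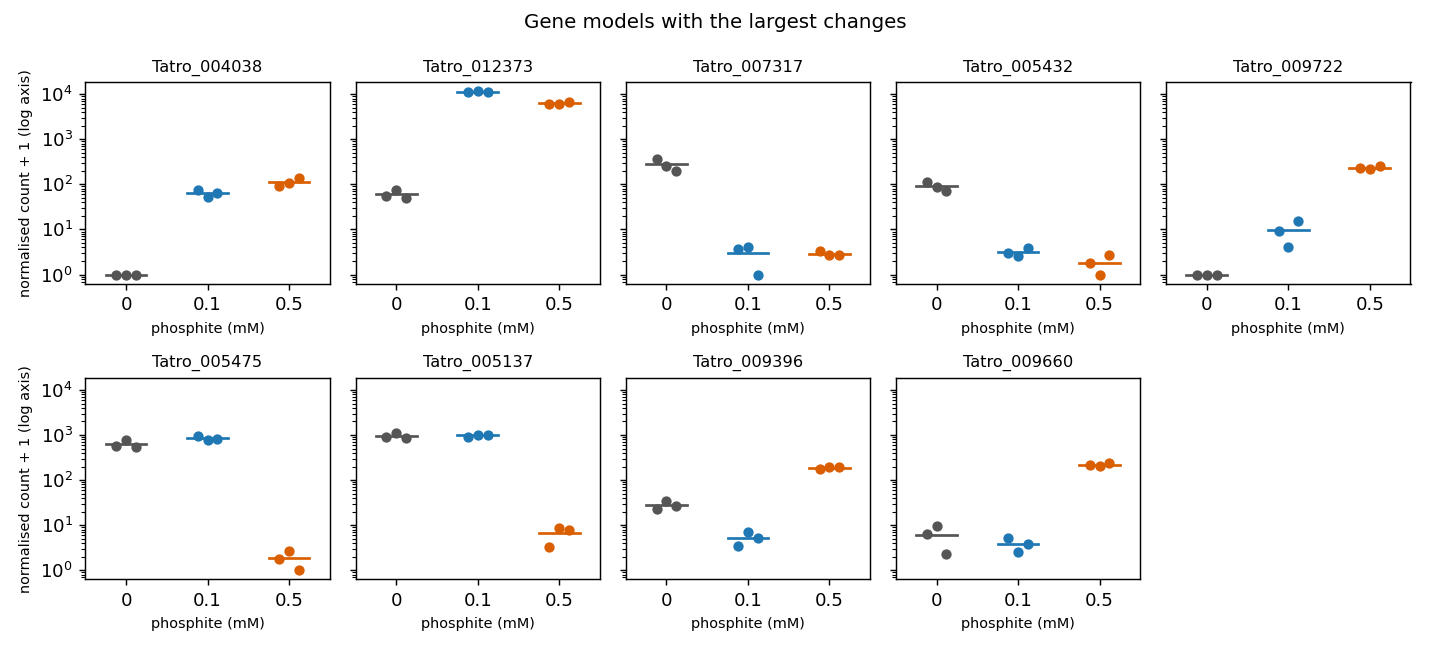
Normalised counts plus 1 (log axis) against phosphite in mM for the 9 gene models with the largest changes. Each point is a library, each bar the mean of 3 libraries, and colour gives the group. Tatro_005475 and Tatro_005137 are low at 0.5 mM alone, and Tatro_007317 and Tatro_005432 at both doses.

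A direct comparison of the doses asked which genes responded differently at 0.5 mM and at 0.1 mM. It gave 3977 changed genes (38.3%), 2041 higher and 1936 lower at 0.5 mM. At least 2-fold differences were found in 1098 genes, 570 higher and 528 lower, and at least 4-fold differences in 254, 119 higher and 135 lower. The median difference of the called genes was 1.56-fold. For 5832 genes (56.2%) the libraries of the doses did not overlap, where chance gives 10%.

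Tatro_009396 and Tatro_009660 showed the largest increases from 0.1 to 0.5 mM. Tatro_009396 rose from 4.31 ± 1.87 to 189 ± 15.3 normalised counts (SD, n = 3), a log2 fold change of 5.91 ± 0.26 (SE; edgeR adjusted p of 9.7e-09). Its control level of 27.0 ± 5.53 lay between the levels at the doses, and it was lower than control at 0.1 mM (log2 fold change -3.11 ± 0.33, edgeR adjusted p of 1.3e-05). At such low counts the fit gives most weight to the deepest library, replicate 1 at 0.1 mM. The gene held 2.449 normalised counts there, against 6.179 and 4.304 in replicates 2 and 3. Tatro_009660 rose from 2.90 ± 1.37 to 218 ± 16 normalised counts, a log2 fold change of 5.80 ± 0.27 (edgeR adjusted p of 1.6e-08), with 5.12 ± 3.64 in the control. Which of them changed more depended on replicate 1 at 0.1 mM: without it the log2 fold changes were 5.13 for Tatro_009396 and 6.51 for Tatro_009660, and with it thinned they were 5.06 and 6.11. The largest decreases between the doses were again in Tatro_005475 and Tatro_005137. Tatro_005475 went from 7442 counts at 0.1 mM to 3 at 0.5 mM, a ratio of 953 between the depth-scaled totals with a counting interval of 326 to 4620 (edgeR adjusted p of 8.2e-10). Its fitted log2 fold change was -9.65, and -10.44 without replicate 2 at 0.5 mM. Tatro_005137 changed by -7.50 ± 0.24 on the log2 scale (edgeR adjusted p of 7.9e-10).

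Each of the 9 gene models named here had values that were not whole in 2 to 8 libraries. Some of their reads were therefore shared with other models, and their levels are uncertain to that extent.

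Together, the calls sorted genes into patterns over the doses. Among patterns with a call, the most frequent was a change at both doses with no difference called between them. It held for 2034 genes (19.6% of those tested), 958 higher and 1076 lower. A change at 0.5 mM with none called at 0.1 mM, and a called difference between the doses, held for 1463 genes, 795 higher and 668 lower. A stepwise change, further from the control at 0.5 mM than at 0.1 mM, held for 810 genes, 444 higher and 366 lower. At 0.1 mM alone, with a called return by 0.5 mM, there were 725 genes, 356 higher and 369 lower. Another 321 genes changed at both doses but lay closer to the control at 0.5 mM, 222 higher and 99 lower. This last count was 205 without replicate 1 of the 0.5 mM group and 196 without its replicate 2. Opposite directions were called in 268 genes, of which 115 were higher and 153 lower at 0.1 mM. Other combinations of calls took 1602 genes, and 3161 had no call in any comparison.

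The division into higher and lower genes within these patterns depended on the scaling, mostly on whether factors beyond library totals were used. For changes at both doses with no difference called it was 967 higher and 1057 lower with RLE factors. With upper-quartile factors it was 916 and 1149. For changes at 0.1 mM alone it was 365 and 347 with RLE factors, and 355 and 373 with upper-quartile factors. With library totals alone it was 1301 higher and 668 lower for changes at both doses with no difference called, 511 and 274 for stepwise changes, 419 and 216 for changes at 0.1 mM alone, and 257 and 57 for genes closer to the control at 0.5 mM. For opposite directions it was 141 higher and 98 lower at 0.1 mM with library totals alone, and 139 and 134 without control replicate 3, so the more frequent direction turned in both.

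**Figure D3:**
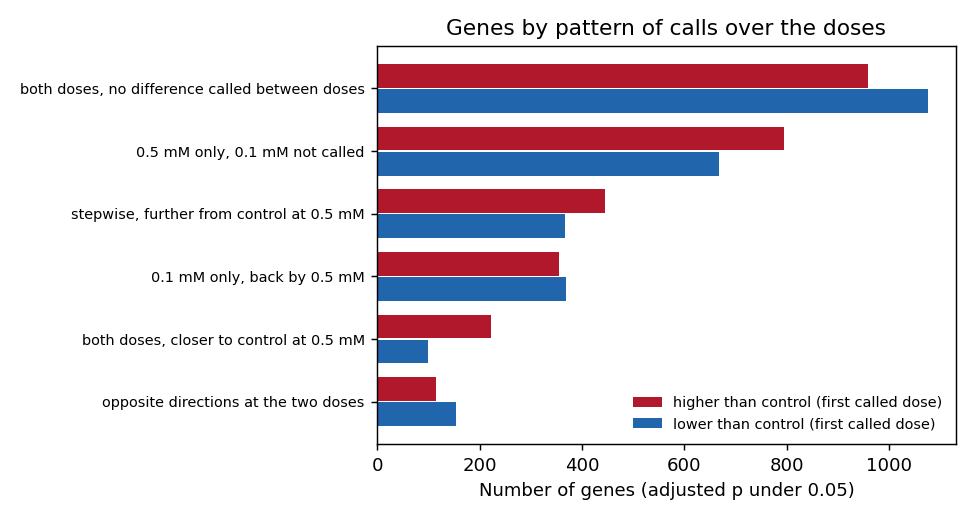
Number of genes (horizontal axis, from 0) in each pattern of calls at an adjusted p under 0.05, with red bars for genes higher and blue bars for genes lower than the control at the lowest dose called. The longest pair of bars, 958 and 1076 genes, is for changes at both doses with no difference called between doses (1301 and 668 with library totals alone).

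Genes with their highest or lowest level at 0.1 mM, with the difference called against the control and against 0.5 mM, numbered 1314 (12.7%). They include the 268 genes called in opposite directions, for which the control lay between the doses. Of the 1314 genes, 693 were higher and 621 lower at 0.1 mM than in both other groups, and with library totals alone 817 were higher and 371 lower. The difference from both was at least 2-fold for 182 genes, 121 higher and 61 lower.

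The last comparisons asked how far the responses to both doses overlapped. In the same direction at both doses, 3165 genes were called, 1624 higher and 1541 lower, which is 68.0% of the calls at 0.1 mM and 56.4% of those at 0.5 mM. Independent lists of these sizes would share 1257 genes, 637 higher and 620 lower. Opposite directions were called in 268 genes, where independent lists would give 1258. Among the 3165 genes, the median absolute log2 fold change was 0.74 at 0.1 mM and 0.89 at 0.5 mM, and 62.1% of genes had the larger change at 0.5 mM. The median ratio of the log2 fold changes was 1.13.

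Both comparisons used the same control libraries, which alone makes fold changes correlate. The Pearson correlation across genes was 0.73, against a mean of 0.54 in 50 simulations of unchanged groups with shared controls. Each gene had the same dispersion in all simulated groups. The covariance was 0.662 against a simulated 0.018, an excess of 0.644. Shared calls in the simulations averaged 0.1 genes and reached 3. With means of 0.3 and 0.5 calls per comparison, this does not show what shared controls add when many genes are called. The 3 control libraries are too few to split so that each part keeps 2 libraries, so part of the excess in shared calls may come from the shared controls.

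**Figure D4:**
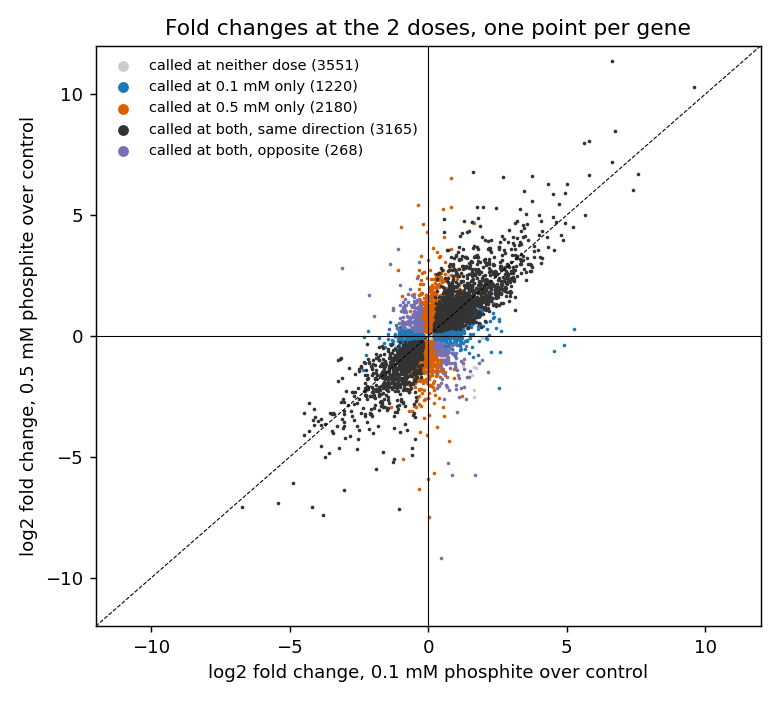
Log2 fold change from the control at 0.1 mM phosphite (horizontal axis) and at 0.5 mM (vertical axis), with 1 point per gene, colour for the comparisons in which it was called, and a dashed line of equal change. The 3165 genes called in the same direction lie in the lower left and upper right, 62.1% of them with the larger change at 0.5 mM, and the 268 genes called in opposite directions lie in the other quadrants. Fitted values of genes with no control count depend on the prior count.

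Averaged over both doses, 5424 genes (52.2%) differed from the control, 2689 higher and 2735 lower. At least 2-fold changes were seen in 1545 genes, 1026 higher and 519 lower, and at least 4-fold changes in 513, 361 higher and 152 lower. With both doses fitted as a group of 6 libraries, so that differences between doses counted as spread, 3536 genes were called. With library totals alone, 64.3% of the calls for the mean of both doses and 67.4% of the calls shared by the doses were higher, in place of 49.6% and 51.3%.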

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

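Counts of changed genes, higher and lower together, stayed within 1.5 times their reported values in most settings. These were DESeq2, other scaling factors, other filters, no robust fitting, fits of the compared groups alone and their libraries left out in turn. In fits of the compared groups alone, 3726 genes changed at 0.1 mM, 5692 at 0.5 mM and 4696 between the doses. The comparison of the doses then gave more calls than 0.1 mM against the control, the reverse of the joint fit. The joint fit shares a spread per gene over all groups. Median absolute log2 deviations of a library from its group were 0.068 to 0.097 at 0.5 mM and 0.133 to 0.157 in the control. No call was lost to the opposite direction in the settings where genes were matched (the replicate block, DESeq2, and without replicate 1 at 0.1 mM or control replicate 3). The exceptions by count follow from their construction. Requiring at least a 2-fold change left 1355 genes at 0.1 mM, 1987 at 0.5 mM, 1098 between the doses, 1545 for the mean of both doses and 975 called at both doses. Fitting both doses as a joint group, chosen after seeing the data, left 3536 genes for their mean. Without each library of the compared groups in turn, the counts ranged from 4147 to 4382 at 0.1 mM, 4782 to 5501 at 0.5 mM, 3031 to 3700 between the doses, 4916 to 5679 for the mean and 2719 to 3110 at both doses, and the correlation of fold changes from 0.73 to 0.76. Without replicate 1 at 0.1 mM, 83.3% of the calls at that dose were kept, and without control replicate 3, 85.5%. Tests added after the data were seen (transcript rows, replicate 1 at 0.1 mM thinned, dose patterns) moved few totals of higher and lower genes by over 1.5 times. The exceptions were the joint group and the 321 genes closer to the control at 0.5 mM. The latter were 205 and 196 without replicates 1 and 2 at 0.5 mM. Lower genes taken alone moved further with library totals alone, from 1076 to 668 for changes at both doses with no difference called. Deviations of libraries with the same replicate number correlated from -0.14 to 0.34, with 5 of 9 pairs over 0.1, and 6 of 9 libraries correlated best with their own number, a hint from the data and not the design. The numbers were therefore not taken as pairs. With the replicate number as a block, 5015, 5897, 4367 and 5708 genes changed in the 4 comparisons, and 3412 at both doses. Gene-list alternatives (estimated correlation, rotation test, block, scaling, libraries left out) were not run because the lists could not be filled. At this depth, a group level under 3 counts, or 1.37 normalised counts in the control, 0.381 at 0.1 mM and 0.991 at 0.5 mM, cannot be told from 0.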

Other observations

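The test for a mislabelled library was chosen after its result was seen, and the runs of genes, the adjacent pairs with whole values, the alternatives for the genes highest or lowest at 0.1 mM and the fit of both doses as a joint group were added after seeing the data. Changed genes lay in runs along the order of the gene models, which is not stated to be genomic order. At 0.1 mM, 30 runs of at least 4 consecutive tested models, all called in the same direction at 2-fold or more, held 148 genes, with 23 runs higher and 7 lower. Shuffled orders gave 0.7 runs on average and 5 at most in 1000. At 0.5 mM there were 49 runs with 228 genes, 36 higher and 13 lower, against 2.0 on average and 8 at most. Between the doses there were 8 runs with 38 genes. The longest run, of 10 models including Tatro_012373, had a median log2 fold change of 4.44 at 0.1 mM. Its mean level was 30.8 normalised counts in the control, 1451.2 at 0.1 mM and 816.4 at 0.5 mM. At both doses that mean came largely from Tatro_012373, at 11400 and 6310 normalised counts. Other genes named above also lay in runs of lower models at 0.5 mM. These were Tatro_005137 in a run of 5, Tatro_005475 in a run of 4 and Tatro_007317 in a run of 7.

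Fold changes at 0.5 mM correlated between adjacent tested models at 0.251, and at 0.050 for models 3 positions apart, above the highest of 1000 shuffled orders, 0.040. A test set beforehand took such a value to exclude reads shared by overlapping neighbours, on the premise that sharing ends at the next model. That premise was not established. Whether a value was whole also correlated between rows 3 positions apart (0.066) and 10 positions apart (0.041), against 0.020 when shuffled. Such a correlation does not trace reads in common, so the reach of sharing is unknown and the test cannot decide. In 116 adjacent pairs where a model had whole values in every library the correlation was 0.134, but shuffles reached 0.273, above the 0.251 of all adjacent pairs, so the pairs were too few to decide. After centring by expression level the correlation 3 positions apart was 0.035, above the highest shuffled value of 0.030, which argues against similar level as the whole cause. Shared reads, copies in tandem included, may account for the pattern and stay open beside clusters of co-regulated genes, for which no biological explanation was tested.

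The 1314 genes with their highest or lowest level at 0.1 mM were examined for technical sources. Their number was 1144 without replicate 1 at 0.1 mM, 1414 without control replicate 3 and 1188 with library totals alone. It was 1109 and 1054 without replicates 2 and 3 at 0.1 mM, and 968 and 977 without replicates 1 and 2 at 0.5 mM. Without control replicates 1 and 2 it was 1284 and 1331. The values 1144 and 1414 argue against the depth of replicate 1 at 0.1 mM and the position of control replicate 3 as the whole cause. Library totals alone mostly traded lower genes for higher ones, with 817 higher and 371 lower in place of 693 and 621. Such a trade leaves the sum nearly unchanged, so 1188 cannot decide on the scaling, although genes in both directions remained. A culture or library batch that follows the groups cannot be told apart from the dose, because 0 of the 9 libraries carry a batch label. A response to phosphite that is not monotonic in dose may be a candidate explanation, as a hypothesis, with the batch and the scaling left open.

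Replicate 1 at 0.1 mM stood apart from replicates 2 and 3. Its median absolute log2 deviation from the others was 0.184 over 7586 genes, against 0.104 and 0.108, and 0.187 after thinning to the depth of replicate 2, which argues against counting depth. Its deviations had an R squared of at most 0.004 on the difference of another group, which argues against RNA of another group mixed in. Its lowest correlation with replicates 2 and 3 was 0.990, above its highest with another group, 0.954, which argues against a mislabelled library. In the control, the same deviation was 0.133 to 0.157 per library, and at 0.5 mM it was 0.068 to 0.097. Within-group pairs with control replicate 3 differed by a median log2 value of 0.218 and 0.238. Those with replicate 1 at 0.1 mM differed by 0.218. Replicates 2 and 3 at 0.1 mM differed by 0.082, and pairs at 0.5 mM by 0.082 to 0.126. By this measure replicates 2 and 3 were alike beside the control, but not beside the 0.5 mM group. Their chi-square per degree of freedom was 2.19, against 3.67 to 8.49 at 0.5 mM. Replicate 1 may thus have deviated, or replicates 2 and 3 may have been unusually alike. The cause stays open, and no biological explanation was tested because the design gives none within a group.

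Other groupings of the libraries were counted for each comparison. With 3 against 3 there are 10 splits, so the share of splits with as many genes cannot fall under 10%. In each of the 3 comparisons between pairs of groups, 1 of 10 splits, the real one, gave as many genes. The real counts were 4653, 5613 and 3977, and the highest of the other splits was 0 by edgeR in each, with up to 990, 235 and 601 genes at an unadjusted p under 0.05. For control against both doses as a joint group, 1 of 84 splits into 3 and 6, the real one, gave as many genes. Every split that broke up a group gave 0, so the 9 libraries were not arranged at random over the groups. Since libraries of a group may be technical replicates, the splits cannot exclude chance differences between cultures. Nor can they exclude a batch or shared origin that follows the groups. The real split gave 3536 genes, the 0.5 mM libraries as the group of 3 gave 2547, the highest other, and the 0.1 mM libraries gave 587.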
